A study of Mus musculus with 8 samples.

How the data were processed

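RNA from 8 mouse livers was measured on an Affymetrix mouse oligonucleotide array, 1 array per mouse, per the labels. The table holds 1 intensity per probe set and array as deposited by the authors. Its values are positive and on a linear scale, which was read from their range and skew. The tool that summarised the probes and the way the arrays were scaled are not given in the sources used here. The groups were taken from the labels: GFP or human LXRα transgene, and vehicle or T0901317, with 2 arrays in each of 4 groups. No sample column of the table was left unused.

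The table held 22690 probe sets, of which 64 were control probe sets and stayed out of the tests. Of the other 22626, 20380 had 1 gene symbol in the probe table provided, 691 had several and 1555 had none. The symbols of 20351 probe sets were updated through their Entrez ID in RefSeq. Intensities were raised to a floor of 7.50, the 20th percentile of positive values without control probe sets, and log2-transformed. The array medians of the log2 intensities lay between 4.39 and 4.53. This range of 0.141 was within the tolerance of 0.2, so the deposited scaling was kept. Probe sets with a mean log2 value above the 30th percentile were tested, 15838 in all, and 9359 genes had at least 1 of them.

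Differences were tested with limma 3.58.1 in R 4.3.3. One fit of 4 group means on all 8 arrays gave a shared estimate of the spread with 4 residual degrees of freedom and 2.93 prior degrees of freedom (eBayes with an intensity trend). Contrasts were the 4 simple comparisons, the interaction, and the transgene and T0901317 effects averaged over the other factor. P-values were adjusted by Benjamini-Hochberg over all probe sets of a contrast, and an adjusted p under 0.05 was called. P-values of single probe sets measure the spread between these samples, and the number of arrays limits the precision. Standard errors (SE) are those of limma after moderation. Unless a sentence names an exact or permutation test, p-values come from limma.

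Gene lists (20 lists with 385 genes) cover LXR targets, fatty acid and triglyceride synthesis, sterol synthesis, bile acids, fatty acid oxidation, glucose metabolism, lipoproteins, xenobiotic metabolism, acute phase and inflammation, interferon response, ER stress, cell cycle and clock output. They also cover markers of hepatocytes, macrophages, stellate cells and matrix, endothelium, lymphocytes, cholangiocytes and erythroid cells. A list was tested with camera (limma) at its preset correlation of 0.01 between genes, with 1 probe set per gene and adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. The preset correlation is lower than most correlations estimated here, which makes its p-values smaller. They compare list members with the other genes and take no correlation between genes from these arrays, so they do not measure the spread between mice. Members were also tested one by one with adjustment over the list alone ("list-adjusted p"). List tests of the averaged comparisons were added after seeing the data.

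A gene was represented by its brightest tested probe set with 1 symbol, and by one ending in x_at only where it had no other. The genes named were set by rule. They are the transgene's mouse counterpart, other receptor genes and Alb, of which 2 were not in the probe table and were not analysed here. They are also the genes with the largest changes in each simple comparison: where fewer than 12 passed, the 6 largest rises and 6 largest falls at an unadjusted p under 0.01 with groups that did not overlap. Up to 4 members of each list described, all measured LXR targets, and up to 8 genes with the smallest adjusted p for the interaction and the averaged effects complete the rule.

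The design, the lists and the following alternatives were set before the data were examined: quantile normalization, centring each array on its median, a floor at the 5th percentile (4.59), an offset in place of a floor, no filter, a filter at the 50th percentile, no intensity trend, robust spread, a block for replicate number, the compared groups alone, each array left out in turn, and other thresholds. Some fits were added after the control probe sets had been seen. These used the log2 β-actin 3'/5' ratio as a covariate or left out the 3 arrays of high ratio. For the macrophage and LXR target lists and the count of averaged T0901317 calls, each of 6 control ratios was used as a covariate. Where an array was left out, its lone partner was assumed to vary like the other groups. Correlations between comparisons that share arrays were set beside 100 simulated draws of unchanged groups, and permutation of genes between lists used 100000 resamples.

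The steps were tested on simulated data, 20 draws with 200 changed probe sets each among 15838. The simulated noise was normal and independent between genes, with the spread that limma estimated, and held no difference in array quality. The shares below describe that setting and do not say how many changes the real comparisons missed. For T0901317 in GFP mice, 26% of 2-fold, 83.8% of 4-fold and 99.1% of 16-fold changes were recovered, with 8.75 false calls per draw. For the averaged T0901317 effect these were 62.4%, 96.3% and 99.8%, with 9.95 false calls per draw. In T0901317 against vehicle in GFP mice with 9359 genes, camera called an LXR target list shifted by 1 on the log2 scale in 20 of 20 draws, and 5 calls fell on other lists.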

Results

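Liver RNA from 8 mice was measured on Affymetrix oligonucleotide arrays, 1 array per mouse. All mice lacked the low density lipoprotein receptor on a C57B6 background and had eaten a Western diet for 12 weeks. At 10 weeks of age they had received an adeno-associated virus (AAV 2.8) in which the human promoter of thyroxine binding globulin, active in liver, drove a transgene, and they were 8 months old at the experiment. The transgene was either GFP, as a control, or human LXRα, the liver X receptor, a nuclear receptor that is activated by oxysterols and controls genes of cholesterol efflux, bile acid synthesis and fatty acid synthesis. Each mouse then received T0901317, a synthetic LXR agonist that also binds the pregnane X receptor, at 5 mg/kg, or vehicle, by intraperitoneal injection for 3 days. The 4 groups (GFP vehicle, GFP T0901317, LXRα vehicle and LXRα T0901317) held 2 arrays each. The median intensity per array lay between 21.0 and 23.2, and arrays of one group correlated with a Pearson r of 0.949 to 0.978 across probe sets. The median absolute log2 difference between the arrays of a group was 0.185 for GFP vehicle and 0.22 for GFP T0901317. It was 0.189 for LXRα vehicle and 0.325 for LXRα T0901317. The fit takes the spread of all groups as equal, and the counts by chance given below rest on that. With 2 arrays per group, the number of arrays limits the precision of every value.

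Mouse Nr1h3, which encodes LXRα, gave intensities of 128 and 170 in GFP vehicle livers, 183 and 218 in LXRα vehicle livers, 75.8 and 98 in GFP T0901317 livers, and 163 and 62.6 in LXRα T0901317 livers. The LXRα vehicle group was 1.35-fold above the GFP vehicle group, a log2 difference of 0.44 (SE 0.45, limma adjusted p = 0.963). The probe set was designed on the mouse gene, and whether it binds RNA of the human transgene is not known, so it does not test the labels. Nr1i2, the pregnane X receptor, had mean log2 intensities of 4.75 in GFP vehicle and 4.82 in LXRα vehicle livers. Alb, the albumin gene, differed by -0.10 between the same groups (SE 0.18, adjusted p = 0.983).

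RNA quality signs differed between the treatments. The ratio of 3' to 5' probe signal of β-actin, which rises when the 5' part of a transcript is lost, was 2.08 to 3.08 on the 4 vehicle arrays. It was 7.56 and 11 on the GFP T0901317 arrays, 36.3 on LXRα T0901317 replicate 2, and 2.75 on LXRα T0901317 replicate 1. The same ratio was 1.67 to 2.20 on vehicle arrays for dap, a bacterial control transcript, against 4.60, 9.97, 21.8 and 2.86 on those T0901317 arrays. By exact two-sided permutation over 70 splits, 4 arrays against 4, the p was 0.0571 for β-actin and 0.0286, the smallest possible, for Gapdh, pyruvate carboxylase, dap and thr; for the bacterial control phe it was 0.229, with a ratio of up to 6.26 on a vehicle array. The 18S ribosomal control probe set gave 245 to 638 on vehicle arrays and 11.8 to 45.3 on T0901317 arrays. By β-actin alone, LXRα T0901317 replicate 1 is called the lower-ratio T0901317 array, and the other T0901317 arrays the 3 higher-ratio arrays. The lower-ratio array was not free of these signs, with ratios above every vehicle array for pyruvate carboxylase (26.4 against at most 11.2), dap, thr (1.28 against 1.10) and Gapdh (1.27 against 1.16), and an 18S signal of 45.3.

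**Figure D1:**
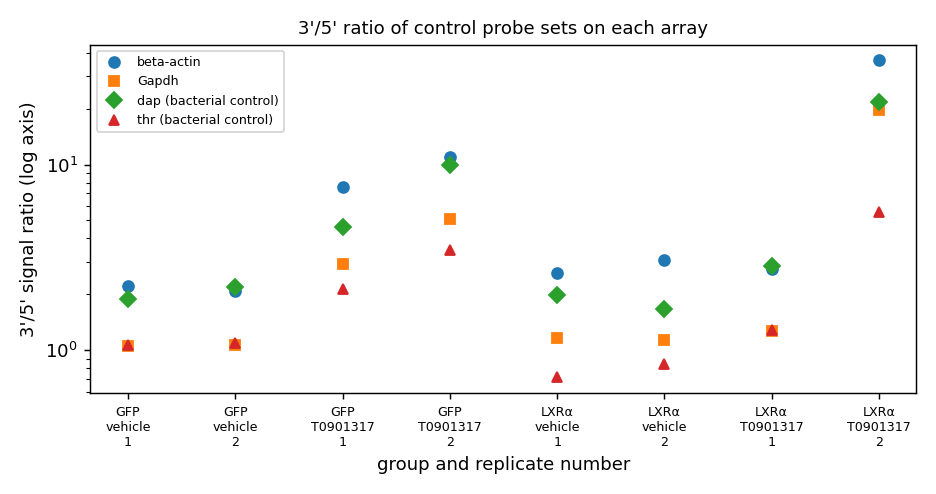
Ratio of 3' to 5' probe signal (log axis) on each of the 8 arrays for β-actin, Gapdh and the bacterial control transcripts dap and thr, 1 point per array and transcript. The β-actin ratio was 2.08 to 3.08 on vehicle arrays, 7.56, 11 and 36.3 on 3 T0901317 arrays and 2.75 on LXRα T0901317 replicate 1.

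The first comparison asked what the LXRα transgene changed in liver without added agonist. Hsd3b5, a hydroxysteroid dehydrogenase of male mouse liver, rose 123-fold in LXRα vehicle over GFP vehicle livers, a log2 difference of 6.94 (SE 0.32, adjusted p = 0.00195). Its mean log2 intensity was 9.90 ± 0.25 (SD, n = 2) against 2.96 ± 0.08 (SD, n = 2). Deposited intensities were 846 and 1080 against 8.10 and 6.82, so the control arrays lay at or next to the floor of 7.50 and the fold depends on that floor. Hsd3b5 was the 1 probe set called of 15838, with 816 at an unadjusted p under 0.05 where 792 would come by chance. The call was lost when 4 arrays were fitted alone (adjusted p = 0.0899) and without the 3 higher-ratio arrays (adjusted p = 0.0688), fits with fewer arrays. The count became 32 without GFP vehicle replicate 1, 2 without GFP vehicle replicate 2 and 3 without LXRα vehicle replicate 1.

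Among LXR target genes, members of both directions passed the test adjusted over the list alone, and none of the 15 measured passed over all probe sets. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 1.63 on the log2 scale (SE 0.30, list-adjusted p = 0.0134), from 6.19 ± 0.14 to 7.82 ± 0.06 (SD, n = 2 each). Abcg8 and Abcg5, which together form the sterol exporter of the bile canaliculus, rose by 1.35 (SE 0.28, list-adjusted p = 0.0134) and 1.23 (SE 0.35, list-adjusted p = 0.0368). Pltp, the phospholipid transfer protein, had a log2 change of -1.42 (SE 0.31, list-adjusted p = 0.0134), from 11.54 ± 0.06 to 10.12 ± 0.62. Differences of the others did not pass: -1.41 for Lpl, 1.04 for Srebf1, -0.77 for Smpdl3a, -0.46 for Abcg1, -0.83 for Apoc2, 0.38 for Mlxipl, -0.18 for Scd1, 0.15 for Lpcat3, 0.08 for Abca1, -0.11 for Mylip and 0.02 for Apoe. The list as a whole had a median of 0.02 (camera adjusted p = 0.912, and 0.963 as adjusted p with an estimated correlation). The bile acid list, with 12 of 18 members higher and Cyp7a1 past the list-alone test, had a median of 0.45 (camera adjusted p = 0.000516; adjusted p = 0.422 with an estimated correlation). Its other leading members were Cyp7b1 at 2.66, Slc27a5 at 0.57 and Hsd3b7 at 0.61. Without LXRα vehicle replicate 1 the camera adjusted p of this list was 0.0566.

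Markers of macrophages, matrix and endothelial cells were lower in LXRα vehicle livers. Of 18 macrophage and Kupffer cell markers, 17 were lower, with a median log2 change of -1.17 (camera adjusted p = 3.33e-12; adjusted p = 0.421 with an estimated correlation); the median was -0.62 on LXRα vehicle replicate 1 and -1.9 on replicate 2. Cd14, the lipopolysaccharide co-receptor, and C1qc, a complement component, fell, adjusted over the list alone, with log2 changes of -2.46 (SE 0.55, list-adjusted p = 0.0414) and -1.57 (SE 0.38, list-adjusted p = 0.0414), while Fcgr1 at -2.27 and Cd68 at -3.10 did not pass. Of 15 stellate cell and matrix markers, 14 were lower, with a median of -0.85 (camera adjusted p = 1.08e-08; adjusted p = 0.421 with an estimated correlation). Lum and Col3a1, a matrix proteoglycan and a fibrillar collagen, fell, adjusted over the list alone, with log2 changes of -1.51 (SE 0.32, list-adjusted p = 0.0285) and -2.38 (SE 0.56, list-adjusted p = 0.0285); another probe set of Col3a1 gave 0.04. The next members were Dcn at -0.96 and Col4a2 at -0.85. Endothelial markers had a median of -0.21, led by Stab1 at -1.08, Lyve1 at -0.98, Esam at -0.51 and Cdh5 at -0.82 (camera adjusted p = 0.00497; adjusted p = 0.519 with an estimated correlation). The camera call of the endothelial list was lost without GFP vehicle replicate 1 (0.067) and without LXRα vehicle replicate 2 (0.457). The β-actin 3'/5' ratio in this comparison was 2.21 and 2.08 in GFP against 2.61 and 3.08 in LXRα livers.

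Further lists stood lower in LXRα vehicle livers. The cell cycle list had a median of -0.26 with 12 of 14 members lower (camera adjusted p = 9.70e-05; adjusted p = 0.421 with an estimated correlation), and Mcm3 and Cdk1 fell, adjusted over the list alone, by 1.03 and 0.75 on the log2 scale (list-adjusted p = 0.0141 and 0.028); other probe sets of Mcm3 gave -0.06, -0.41 and -0.12. Cdc20 followed at -0.39. Genes of fatty acid oxidation under PPARα had a median of -0.30, led by Cyp4a14 at -4.01, Cd36 at -2.05, Plin2 at -0.86 and Ehhadh at -1.13 (camera adjusted p = 0.000672; adjusted p = 0.519 with an estimated correlation). Genes of xenobiotic metabolism had a median of -0.29, led by Gstm3 at -3.42, Gstm1 at -2.02, Abcc3 at -1.4 and Gsta2 at -2.88 (camera adjusted p = 0.00152; adjusted p = 0.519 with an estimated correlation). Fatty acid and triglyceride synthesis genes had a median of -0.34, led by Scd2 at -1.58, Elovl5 at -0.76, Dgat2 at 0.53 and Pgd at -0.87 (camera adjusted p = 0.0155; adjusted p = 0.539 with an estimated correlation). No single member of the last 3 lists passed, adjusted over the list alone. Without LXRα vehicle replicate 2 the camera adjusted p was 0.179 for fatty acid oxidation and 0.569 for xenobiotic metabolism, and the fatty acid synthesis list turned direction (0.462); without GFP vehicle replicate 1 the last was 0.0687.

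The remaining genes with the largest differences, ranked among those at an unadjusted p under 0.01 with groups that did not overlap, did not pass the threshold. Higher in LXRα vehicle livers were Nnmt by 3.24 (SE 0.89), Slc22a7 by 3 (SE 0.61), C8b by 2.41 (SE 0.48) and Cyp2c70 by 1.86 (SE 0.25), and Cyp7b1 had an SE of 0.68, with adjusted p between 0.299 and 0.767. On the other side Ly6d differed by -5.12 (SE 0.53), Cbr3 by -2.93 (SE 0.74), Sprr1a by -2.78 (SE 0.44) and Anxa2 by -2.65 (SE 0.55; -0.11 for another probe set), with adjusted p between 0.105 and 0.685. Cyp4a14 and Gstm3 (SE 1.13 and 0.74, adjusted p = 0.774 and 0.58) also belonged to this group. The LXRα vehicle mean of Cbr3 lay at the floor of 7.50, against 57.2 in GFP vehicle livers, so its difference depends on that floor.

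The second comparison asked what T0901317 changed in livers with the control transgene. Cyp7a1 was 8.54-fold higher after T0901317, a log2 difference of 3.09 (SE 0.30) that passed adjusted over the list alone (list-adjusted p = 0.000266) and not over all probe sets (adjusted p = 0.0702). Abcg8, Abcg5, Abca1, Srebf1 and Mlxipl also rose, adjusted over the list alone. Their log2 changes were 1.61 (SE 0.28), 1.74 (SE 0.35), 1.17 (SE 0.26), 1.80 (SE 0.49) and 1.10 (SE 0.32), with list-adjusted p of 0.0055 to 0.0283. Abca1 encodes the cellular cholesterol exporter, Srebf1 the transcription factor SREBP-1, and Mlxipl the carbohydrate response factor ChREBP. Of the 15 LXR targets measured, 12 were higher, with a median of 0.27 (camera adjusted p = 0.00584; adjusted p = 0.896 with an estimated correlation; 0.0633 with the mean of a gene's probe sets). The members that did not pass had differences of -0.28 for Apoe, -0.54 for Apoc2, 0.15 for Scd1, 0.46 for Mylip, 0.20 for Abcg1, 0.23 for Pltp, 0.18 for Lpcat3, 0.27 for Lpl and -0.01 for Smpdl3a. Both T0901317 arrays of this comparison had β-actin 3'/5' ratios above every vehicle array, and 2 other probe sets of Abca1 went the other way, with differences of -1.18 and -2.43.

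Cyp8b1, the sterol 12α-hydroxylase of cholic acid synthesis, fell, adjusted over the list alone, with a log2 change of -1.70 (SE 0.38, list-adjusted p = 0.025), from 8.78 ± 0.15 to 7.08 ± 0.40 (SD, n = 2 each). The bile acid list as a whole had 9 members higher and 9 lower, among them the transporters Abcb11 at 1.07 and Abcc2 at 1.03 (camera adjusted p = 0.947). Cdk1 and Cdc20 fell, adjusted over the list alone, with changes of -1.07 (SE 0.18) and -0.56 (SE 0.12), although another probe set of Cdc20 gave 0.03. The cell cycle list, with Mcm3 at -0.51 and Ccne1 at -0.59 next, had a median of -0.28 (camera adjusted p = 0.00655; adjusted p = 0.896 with an estimated correlation; 0.113 with the filter at the 50th percentile). Fatty acid synthesis genes had a median of 0.335, with Elovl6 at 2.29, Acacb at 2.58, Acss2 at 1.87 and Elovl1 at -1.37, and were not called (camera adjusted p = 0.191). The interferon list had a median of -0.61, with Ifit3 at -1.12, Psmb8 at -0.90, Usp18 at -1.29 and Ifit1 at -1.08 (camera adjusted p = 0.0341; adjusted p = 0.896 with an estimated correlation; 0.0633 with the mean of a gene's probe sets). With the β-actin ratio as a covariate, chosen after seeing the data, the interferon list was at 0.652. Without GFP vehicle replicate 1 the camera adjusted p was 0.676 for interferon and 0.0798 for cell cycle, and without GFP T0901317 replicate 2 the interferon list was at 0.0559.

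Over all probe sets limma called 0 in this comparison, with 2083 at an unadjusted p under 0.05 against 792 by chance and 10 under an adjusted p of 0.10. Largest differences were ranked among genes at an unadjusted p under 0.01 with groups that did not overlap. Upward, besides Cyp7a1, they were Fabp5 at 4.12 (SE 0.58), a fatty acid binding protein, Hamp at 3.59 (SE 0.85) and Hamp2 at 2.99 (SE 0.80), the hepcidin genes of iron control, Aak1 at 2.89 (SE 0.30) and Zmynd8 at 2.43 (SE 0.22), with adjusted p between 0.0641 and 0.23. Downward they were Cd99 at -3.41 (SE 0.89), Hnrnpab at -3 (SE 0.49), Sprr1a at -2.83 (SE 0.44), Tnfrsf12a at -2.78 (SE 0.70), Ggact at -1.92 (SE 0.36) and Tug1 at -1.73 (SE 0.41), with adjusted p between 0.138 and 0.223. Aak1, Hnrnpab and Tug1 each had another probe set of the opposite sign, at -0.09, 0.71 and 1.12. The remaining probe sets of Hnrnpab were lower too, at -1.13 to -0.12. The GFP T0901317 mean of Cd99 lay at the floor of 7.50, against 79.7 in GFP vehicle livers, so its difference depends on that floor. The count was 33 without GFP vehicle replicate 1, 1 without GFP vehicle replicate 2, 3 without GFP T0901317 replicate 1, and 38 and 43 without LXRα T0901317 replicates 1 and 2, which enter here only through the shared spread.

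**Figure D2:**
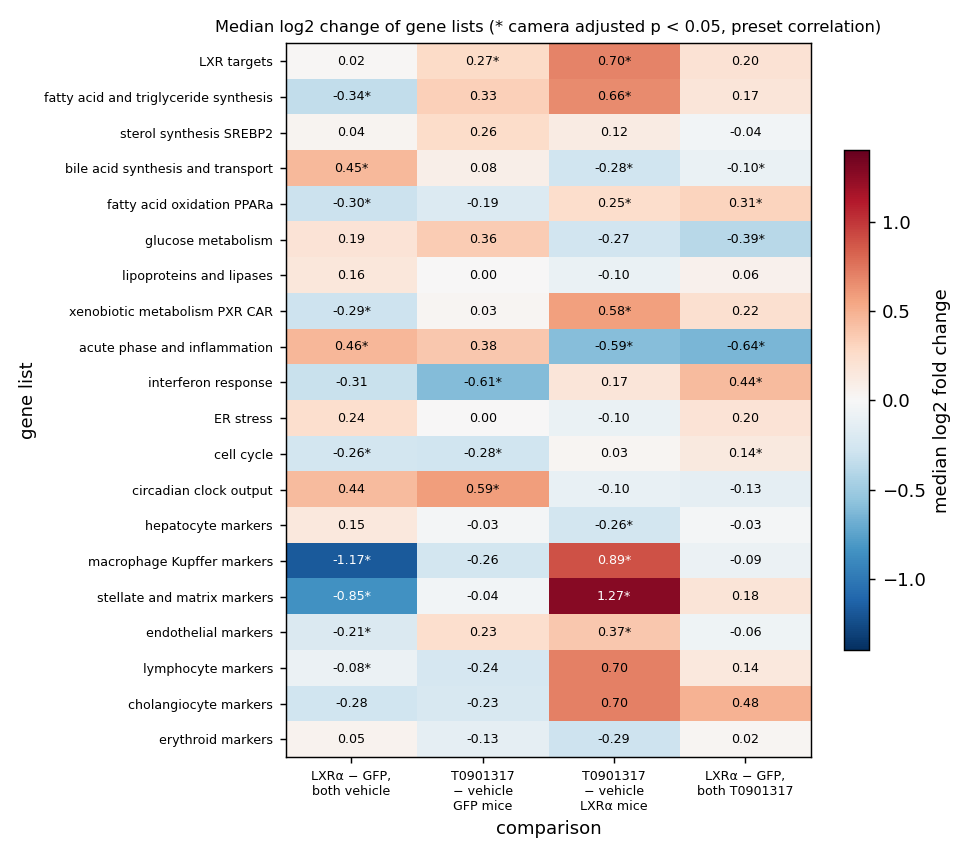
Median log2 change of each of the 20 gene lists (top to bottom) in the 4 simple comparisons (left to right), with colour and number giving the median over the measured members and an asterisk marking a camera adjusted p under 0.05 with the preset correlation. Macrophage and matrix markers were at -1.17 and -0.85 in LXRα against GFP under vehicle, and at 0.89 and 1.27 after T0901317 in LXRα mice, a comparison with the same LXRα vehicle arrays; none of the calls held with an estimated correlation.

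The third comparison asked what T0901317 changed in livers with the LXRα transgene. Hsd3b5 fell, with a log2 change of -6.49 (SE 0.32, adjusted p = 0.00307) and deposited intensities of 5.75 and 15 around the floor of 7.50. Zmynd8, a chromatin reader, rose by 2.65 (SE 0.22, adjusted p = 0.0358) and Mast2, a kinase, by 1.71 (SE 0.16, adjusted p = 0.0488). With 1 probe set that has no gene symbol or several, at 3.27 (adjusted p = 0.0104), these made 4 calls, against 2087 probe sets at an unadjusted p under 0.05 and 792 by chance. Without a filter on dim probe sets the count was 14, of which 3 higher and 11 lower. The count was 7, of which 6 higher and 1 lower, after quantile normalization, 0 with the 4 arrays fitted alone and 9 without the 3 higher-ratio arrays, the last chosen after seeing the data. It was 0 without LXRα vehicle replicate 2, where Hsd3b5 had an adjusted p of 0.068, and 474 without LXRα T0901317 replicate 1, the lower-ratio array.

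Of the 15 LXR targets, 14 were higher, with a median of 0.70 (camera adjusted p = 1.04e-05; adjusted p = 0.493 with an estimated correlation). Pltp rose by 1.97 (SE 0.31), Lpl, the lipoprotein lipase, by 2.13 (SE 0.58), Cyp7a1 by 1.22 (SE 0.30), Abca1 by 0.94 (SE 0.26), Scd1, the stearoyl-CoA desaturase, by 0.51 (SE 0.17) and Abcg1 by 0.70 (SE 0.23). All 6 passed adjusted over the list alone, with p from 0.00616 to 0.0475, and none over all probe sets. The others had differences of 0.96 for Smpdl3a, 0.83 for Abcg5, 0.54 for Abcg8, 0.89 for Mylip, 0.52 for Lpcat3, 0.64 for Srebf1, 0.60 for Apoc2, -0.17 for Apoe and 0.21 for Mlxipl. On the lower-ratio array 14 of the 15 were above the LXRα vehicle mean, with a median of 0.75, and on the higher-ratio array 13, with a median of 0.665. Another probe set of Scd1 gave -0.20, that of Cyp7a1 0.05, and those of Abca1 gave -1.99 and -1.18. Pltp and Lpl rose from low LXRα vehicle values, which differed from GFP vehicle livers by -1.42 and -1.41. Neither passed after T0901317 in GFP mice.

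Fatty acid synthesis genes were higher by a median of 0.66, with 16 of 20 members up (camera adjusted p = 0.000419; adjusted p = 0.493 with an estimated correlation). Scd2, Elovl6, the long-chain fatty acid elongase, Acss2 and Fasn, the fatty acid synthase, rose by 4.05 (SE 0.58), 3.14 (SE 0.51), 2.36 (SE 0.65) and 1.99 (SE 0.56), adjusted over the list alone (list-adjusted p = 0.00453 to 0.0478). The median was 0.81 on the lower-ratio and 0.84 on the higher-ratio array. Fatty acid oxidation genes had a median of 0.25 (camera adjusted p = 0.0058; adjusted p = 0.543 with an estimated correlation), and Ehhadh, Pdk4 and Cyp4a14 rose by 2.98 (SE 0.59), 2.88 (SE 0.64) and 5.06 (SE 1.13), adjusted over the list alone (list-adjusted p = 0.0208 each), with Acot1 next at 3.42; the median of the list was 0.447 on the lower-ratio and 0.0555 on the higher-ratio array. Xenobiotic genes had a median of 0.58 (camera adjusted p = 0.00528; adjusted p = 0.493 with an estimated correlation), and Gstm3, a glutathione transferase, and Cyp2c55 rose by 4.42 (SE 0.74) and 2.48 (SE 0.42), adjusted over the list alone (list-adjusted p = 0.00701 each), with Gstm1 at 1.96 and Ces2a at 1.54 next; the list medians on the 2 arrays were 0.582 and 0.498. Without LXRα T0901317 replicate 1 the camera adjusted p of these lists was 0.0808, 0.364 and 0.0895, and without LXRα vehicle replicate 2 that of fatty acid oxidation was 0.0967 and of xenobiotic genes 0.113.

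The bile acid list went the other way, with 14 of 18 members lower and a median of -0.28 (camera adjusted p = 0.00178; adjusted p = 0.493 with an estimated correlation). Slco1b2 and Slc10a1, hepatocyte uptake transporters, had log2 changes of -1.48 (SE 0.23) and -1.19 (SE 0.36). The enzymes Cyp8b1 and Cyp7b1 were at -2.17 (SE 0.38) and -3.22 (SE 0.68), and Nr0b2, the repressor SHP, at -1.50 (SE 0.32). With Hsd3b7 at -0.85 and Amacr at -0.65, these 7 fell and Cyp7a1 rose, adjusted over the list alone. The median of the list was -0.38 on the lower-ratio and -0.395 on the higher-ratio array. Acute phase genes had 23 of 27 members lower and a median of -0.59, with Cxcl1 at -2.09, Lbp at -1.33, Saa4 at -1.70 and Vcam1 at 2.29 (camera adjusted p = 0.000438; adjusted p = 0.493 with an estimated correlation). Without LXRα vehicle replicate 2 the acute phase list was at 0.075.

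Markers of stellate cells and matrix were higher in 14 of 15 members, with a median of 1.27 (camera adjusted p = 1.94e-07; adjusted p = 0.493 with an estimated correlation). Col4a2, Dcn, Sparc, Col3a1, Lum, Pdgfrb, Reln and Col1a1 rose, adjusted over the list alone, by 1.15 to 2.54 on the log2 scale; the largest of these was Col3a1 at 2.54 (SE 0.56) and the smallest Reln at 1.15 (SE 0.33). Other probe sets gave 0.11 for Col3a1, 0.24 for Col1a1 and -0.07 for Pdgfrb. The list's median was 1.26 on the lower-ratio and 1.04 on the higher-ratio array. Against GFP vehicle livers, the LXRα vehicle arrays used here were low, with medians of -0.85 for matrix and -1.17 for macrophage markers. Macrophage markers had a median of 0.89, with Mpeg1 at 1.13, Gpnmb at 2.57, C1qc at 1.09 and Fcgr1 at 1.67 and none past the list-alone test (camera adjusted p = 0.00178; adjusted p = 0.493 with an estimated correlation). Endothelial markers had a median of 0.375 (camera adjusted p = 0.00445; adjusted p = 0.493 with an estimated correlation), and Lyve1 rose by 2.89 (SE 0.41, list-adjusted p = 0.00268), with Stab1 at 1.04, Cdh5 at 1.5 and Esam at 0.72 next. Hepatocyte markers had a median of -0.26, with Asgr1 at -0.89, Cyp2e1 at -0.50, Fgb at -0.67 and Ahsg at -0.66 (camera adjusted p = 0.0428; adjusted p = 0.493 with an estimated correlation; 0.307 without the 3 higher-ratio arrays, 0.276 with the β-actin covariate, 0.0843 after quantile normalization, and 0.106 and 0.241 without LXRα vehicle replicate 1 and LXRα T0901317 replicate 2). Ccnd1, cyclin D1, rose by 3.36 (SE 0.47, list-adjusted p = 0.00275) and Mcm3 by 0.81 (SE 0.19, list-adjusted p = 0.0268), although 2 other probe sets of Mcm3 gave -0.14 and -0.18; the cell cycle list, with Mcm6 at 1.09 and Rrm2 at 1.10, was not called (camera adjusted p = 0.207). Without LXRα vehicle replicate 2 and without LXRα T0901317 replicate 1, the camera adjusted p was 0.246 and 0.104 for macrophage and 0.0967 and 0.117 for endothelial markers.

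Other genes were ranked among those at an unadjusted p under 0.01 with groups that did not overlap. The largest differences that did not pass over all probe sets included Ly6d at 4.40 (SE 0.53), Ccl9 at 3.62 (SE 0.84) and Hamp2 at 3.39 (SE 0.80) upward. Slc22a7 at -4.60 (SE 0.61), Qsox1 at -2.76 (SE 0.71) and C8b at -2.19 (SE 0.48) lay downward, and the adjusted p of these 6 lay between 0.092 and 0.207. Ly6d, Gstm3, Cyp4a14, Slc22a7, Cyp7b1, C8b and Hsd3b5 had differences of the opposite sign in the first comparison, which shares the LXRα vehicle arrays.

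**Figure D3:**
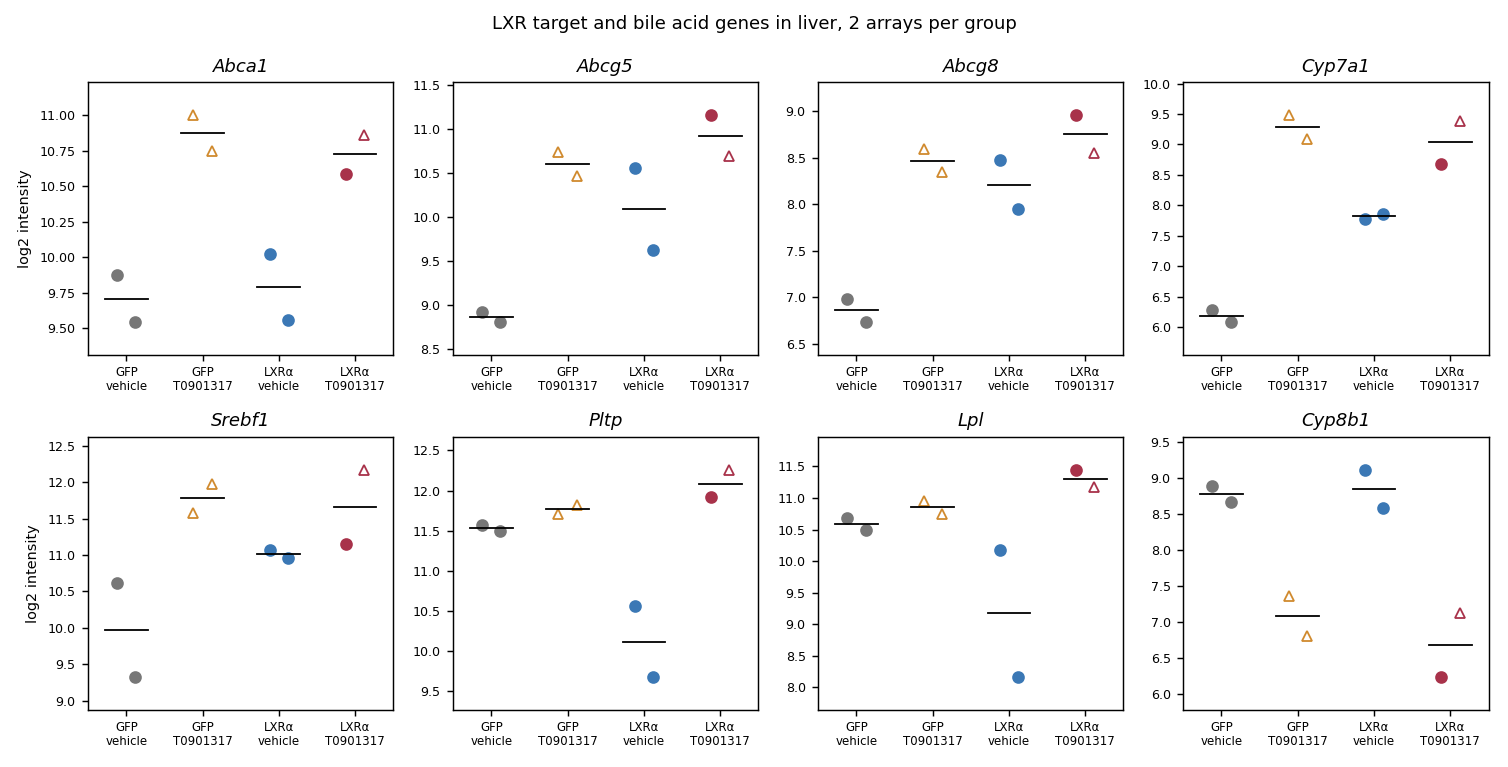
Log2 intensity of LXR target and bile acid genes on each array (2 points per group; open triangles are arrays with a β-actin 3'/5' ratio above every vehicle array, filled circles the others, bars the mean of 2). Cyp7a1 had means of 6.19 in GFP vehicle, 9.28 in GFP T0901317, 7.82 in LXRα vehicle and 9.04 in LXRα T0901317 livers.

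The fourth comparison asked what the LXRα transgene changed in agonist-treated livers. None of the 15 LXR targets passed, adjusted over the list alone, and their median was 0.20 (camera adjusted p = 0.266). The differences ran from -0.51 for Mlxipl to 0.48 for Lpcat3, with Scd1 at 0.18, Abcg8 at 0.29, Pltp at 0.32, Abcg5 at 0.32, Cyp7a1 at -0.24, Lpl at 0.45, Apoe at 0.12, Mylip at 0.32, Apoc2 at 0.30, Abca1 at -0.15, Smpdl3a at 0.20, Srebf1 at -0.12 and Abcg1 at 0.04. Acute phase genes were lower in LXRα livers in 23 of 27 members, with a median of -0.64 and with Lcn2 at -2.16, Saa4 at -1.47, Cxcl1 at -1.28 and Orm2 at -2.47 (camera adjusted p = 6.88e-08; adjusted p = 0.544 with an estimated correlation). Fatty acid oxidation genes were higher in 19 of 21, with a median of 0.31 and with Plin2 at 1.01, Acot2 at 0.45, Pdk4 at 1.33 and Acot1 at 1.80 (camera adjusted p = 0.000559). Interferon genes were higher in 17 of 19, with a median of 0.44 and with Mx1 at 0.49, Ifit1 at 1.62, Usp18 at 1.60 and Oas1a at 0.95 (camera adjusted p = 0.000559). Both had an adjusted p of 0.544 with an estimated correlation. The β-actin ratios were 7.56 and 11 in GFP against 2.75 and 36.3 in LXRα livers.

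Macrophage markers had a median of -0.09 with 12 of 18 lower (camera adjusted p = 0.546) and matrix markers one of 0.18 with 12 of 15 higher (0.0958). Of the other lists of this comparison, glucose metabolism had a median of -0.39 with Ppargc1a at -1.31, Fbp1 at -0.51, Pcx at -0.54 and Pfkl at -0.44 (camera adjusted p = 0.00369). Bile acid genes were at -0.10 with Abcb11 at -0.73, Abcc2 at -0.64, Akr1d1 at -0.78 and Slc10a1 at -0.73 (camera adjusted p = 0.00833). Cell cycle genes were at 0.14 with Ccnd1 at 1.56, Cdk1 at 0.37, Mcm6 at 0.62 and Rrm2 at 0.59 (camera adjusted p = 0.0033). Each of these 3 had an adjusted p of 0.544 with an estimated correlation, and no member of any list passed, adjusted over the list alone. Without LXRα T0901317 replicate 1 the camera adjusted p was 0.809 for fatty acid oxidation, 0.603 for interferon, 0.22 for bile acid and 0.0871 for cell cycle genes. Without GFP T0901317 replicate 2 fatty acid oxidation was at 0.889. Without GFP T0901317 replicate 1 glucose metabolism, bile acid and cell cycle genes were at 0.0858, 0.617 and 0.208, and without LXRα T0901317 replicate 2 at 0.255, 0.12 and 0.158.

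By single probe sets limma called 0 in this comparison, with 355 at an unadjusted p under 0.05 against 792 by chance and 0 under an adjusted p of 0.10. Genes were ranked among those at an unadjusted p under 0.01 with groups that did not overlap. The largest of these differences were Cyp2c55 at 1.72 (SE 0.42), Mast2 at 1.05 (SE 0.16), Synpo at 0.87 (SE 0.20), Defb1 at 0.81 (SE 0.22), Prkra at 0.70 (SE 0.20) and Aspscr1 at 0.67 (SE 0.18) upward, and Slc22a7 at -2.38 (SE 0.61), Zfp955b at -1.30 (SE 0.29), Clstn3 at -1.20 (SE 0.23), Cdh2 at -1.17 (SE 0.31), Celsr1 at -1.14 (SE 0.17) and Csf2rb2 at -1.12 (SE 0.22) downward. All had an adjusted p of 1, and another probe set of Zfp955b gave 0.33. The count was 5 without GFP T0901317 replicate 1, and 1 and 2 without LXRα T0901317 replicates 1 and 2.

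The interaction asked whether the response to T0901317 differed between the transgenes. Hsd3b5 was the 1 call, with a response that was lower in LXRα than in GFP mice by a log2 difference of -6.52 (SE 0.45, adjusted p = 0.0314), and 755 probe sets had an unadjusted p under 0.05. Within the LXR targets Cyp7a1 responded less in LXRα mice, at -1.88 (SE 0.42), and Pltp more, at 1.74 (SE 0.44), both adjusted over the list alone (list-adjusted p = 0.0421). Both genes differed more between the transgenes under vehicle than under T0901317, so these values come mainly from the vehicle groups. The other members did not pass, with Abcg8 at -1.06, Lpl at 1.86, Mlxipl at -0.88, Abcg5 at -0.91, Smpdl3a at 0.97, Srebf1 at -1.16, Abcg1 at 0.50, Apoc2 at 1.14, Scd1 at 0.36, Lpcat3 at 0.33, Abca1 at -0.23, Mylip at 0.43 and Apoe at 0.11. Mcm3, Cdk1, Ccnd1 and Mcm6 responded more in LXRα mice, at 1.31, 1.12, 2.62 and 1.67, and Gstm3 at 5.15 (SE 1.04), adjusted over their lists alone. The Hsd3b5 adjusted p was 0.0501 after quantile normalization, 0.137 with the lower floor, 0.14 without a filter and 0.0824 with the replicate block. Leaving out GFP vehicle replicate 2, GFP T0901317 replicate 1 or 2, or LXRα vehicle replicate 1 or 2 gave 0.112, 0.0973, 0.415, 0.0716 and 0.288, with log2 differences of -6.7 to -6.35. The count was 24 without GFP vehicle replicate 1, 4, 2, 2 and 4 without GFP T0901317 replicate 1, LXRα vehicle replicate 1, and LXRα T0901317 replicates 1 and 2, and 0 without GFP vehicle replicate 2, GFP T0901317 replicate 2 and LXRα vehicle replicate 2.

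**Figure D4:**
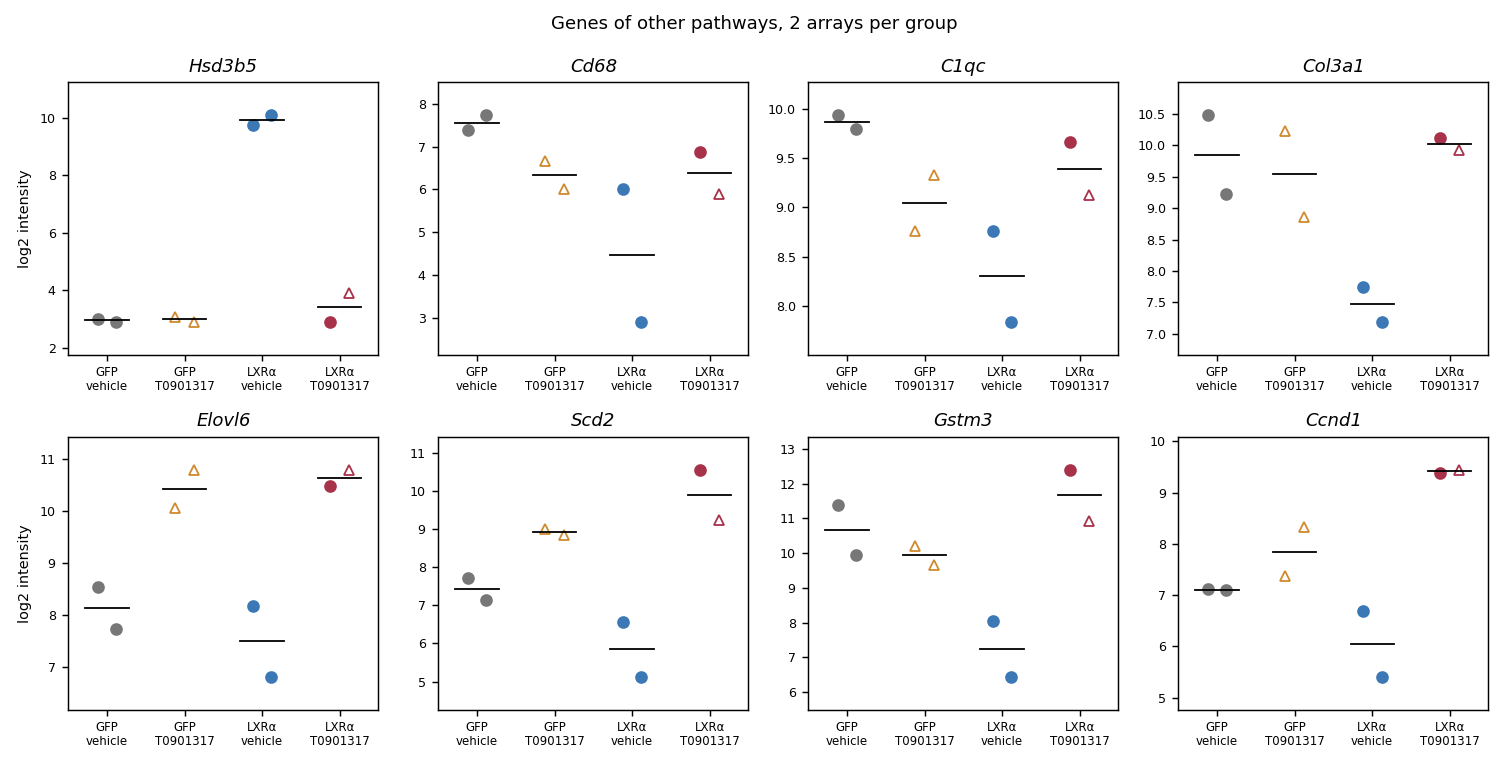
Log2 intensity on each array of 8 genes of steroid metabolism, macrophages, matrix, lipogenesis, detoxification and cell cycle (2 points per group; open triangles are arrays with a β-actin 3'/5' ratio above every vehicle array, filled circles the others, bars the mean of 2). Hsd3b5 had a mean of 9.90 in LXRα vehicle livers and between 2.96 and 3.41 in the other groups.

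Averaged over the transgenes, with 4 arrays against 4, T0901317 changed 90 probe sets, 68 higher and 22 lower, and 47 genes by their brightest probe set, 40 higher and 7 lower. Cyp7a1 rose 4.46-fold, a log2 change of 2.16 (SE 0.21, adjusted p = 0.025). Zmynd8 rose by 2.54 (SE 0.16, adjusted p = 0.014), Aak1 by 2.23 (SE 0.21, adjusted p = 0.025), Rnf145 by 2.01 (SE 0.17, adjusted p = 0.0206), Mtdh by 1.74 (SE 0.14, adjusted p = 0.0206) and Cd93 by 1.31 (SE 0.13, adjusted p = 0.025). Hsd3b5 fell by 3.23 and Mia2 by 0.88, with adjusted p of 0.0166 and 0.025; the Hsd3b5 value averages the change of -6.49 in LXRα mice with GFP mice, where it lay around the floor in both arms (8.10 and 6.82 against 8.40 and 6.59). Of listed genes, the lipogenic Elovl6 and Scd2 rose by 2.72 (SE 0.36) and 2.77 (SE 0.41), Lyve1 by 2.05 (SE 0.29), and Cyp8b1 fell by 1.93 (SE 0.27). Of the 15 LXR targets, 10 rose, adjusted over the list alone, and Cyp7a1 also over all probe sets; the median was 0.68 (camera adjusted p = 2.52e-05; adjusted p = 0.771 with an estimated correlation), a list test added after seeing the data.

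The number of averaged calls depended on the fit. With other control 3'/5' ratios as a covariate, chosen after seeing the data, it was 4 for Gapdh or thr. It was 0 for pyruvate carboxylase, dap or phe. With the β-actin 3'/5' ratio as a covariate 4 probe sets were called, 2 of them among the 90, and all 90 had the direction they had without it; Cyp7a1 was then at 1.82 (adjusted p = 0.114, and 0.00781 to 0.179 over all alternatives) and Hsd3b5 at -3.74. Of 3279 genes with several tested probe sets, 1681 had at least 1 with an unadjusted p under 0.05 for T0901317, and in 146 of those a pair of probe sets had such p in opposite directions, against 1 of 216 for the averaged transgene effect. Aak1, Cd93 and Mtdh each had another probe set of the opposite sign, at -0.31, -0.20 and -0.29, and that of Cyp7a1 was at 1.06. Centring each array on its median gave 95 higher and 16 lower. Without a filter there were 7 higher and 8 lower. Leaving out GFP vehicle replicate 1 gave 43 calls (9 higher, 34 lower), replicate 2 gave 9 (3 and 6), GFP T0901317 replicate 1 gave 7 (6 and 1) and replicate 2 gave 1 (higher). Leaving out LXRα vehicle replicate 1 gave 1 (lower), replicate 2 gave 0, LXRα T0901317 replicate 1 gave 1506 (757 and 749) and replicate 2 gave 16 (14 and 2).

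Averaged over the treatments, the LXRα transgene changed 1 probe set, Hsd3b5, at 3.68 (SE 0.23, adjusted p = 0.0139), with 422 at an unadjusted p under 0.05. The Hsd3b5 value averages 6.94 under vehicle with 0.42 under T0901317, where all 4 arrays lay between 5.75 and 15, around the floor of 7.50. Macrophage markers were lower in 17 of 18 members, with a median of -0.68 and with Cd14 at -1.37 and Cd68 at -1.53 (camera adjusted p = 9.01e-11; adjusted p = 0.972 with an estimated correlation). Matrix markers had a median of -0.35, with Lum at -0.96 (camera adjusted p = 0.000807; adjusted p = 0.972 with an estimated correlation). Under T0901317 alone the medians were -0.09 for macrophage markers (camera adjusted p = 0.546) and 0.18 for matrix markers (0.0958), so these averages come mainly from the vehicle arrays. Endothelial markers were lower in 11 of 12 members, with an averaged median of -0.12 (camera adjusted p = 0.0286, and 0.972 with an estimated correlation). Their median under T0901317 alone was -0.06 (camera adjusted p = 0.726). Hsd3b5 was lost without a filter (adjusted p = 0.0992), with the lower floor (0.0905), and without GFP vehicle replicate 2 (adjusted p = 0.193), GFP T0901317 replicate 2 (0.241) and LXRα vehicle replicates 1 and 2 (0.0548 and 0.142). The count was 31 without GFP vehicle replicate 1, 5 without GFP T0901317 replicate 1, 2 and 3 without LXRα T0901317 replicates 1 and 2, and 0 without GFP vehicle replicate 2, GFP T0901317 replicate 2 and LXRα vehicle replicate 2.

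The responses to T0901317 in the 2 transgene backgrounds share no array, and across 15838 probe sets their log2 changes correlated at r = 0.509, against -0.01 for simulated unchanged groups. Genes are not independent replicates, and 3 of the 4 T0901317 arrays shared the high 3'/5' ratios. At an adjusted p under 0.10, 6 probe sets were higher in GFP and 20 in LXRα mice, with 2 in both against 0.00758 for independent lists. The effects of the transgene and of T0901317 against the same GFP vehicle arrays correlated at 0.394. Unchanged groups against shared controls gave 0.50, and the covariance was 0.10 against a simulated 0.0577, so part of the correlation may be carried by those arrays. The transgene effects under vehicle and under T0901317 correlated at -0.154.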

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

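The tests on the macrophage markers and on Hsd3b5, and those with control ratios as covariates, in this part were chosen only after the result was seen. Values are set out here where the response to T0901317 differed between LXRα and GFP mice in a test of that difference, or where a signal outside the main measurement lay above every vehicle array.

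Hsd3b5 responded differently by a log2 value of -6.52 (limma adjusted p = 0.0314; 0.0055 to 0.415 over the alternatives). It was between 5.75 and 15 on 6 arrays, around the floor of 7.50, and high on both LXRα vehicle arrays. A fall in GFP mice could therefore not have been seen. Hsd3b5 is a gene of male mouse liver, and the highest Xist value on any array was 1.33 times the 20th percentile of all values while the lowest Eif2s3y value was 11.3 times it, which argues against female animals in the other groups. The higher of the LXRα T0901317 arrays reached 0.0155 of the LXRα vehicle mean, although these mice carry the same transgene. This argues against transgene RNA on the probe set only if both LXRα groups made similar amounts of it, which could not be checked here. The low values were also part of the pattern that was flagged. An effect of the transgene that the agonist removes, or another state that the 2 LXRα vehicle mice shared, such as hormone status, may explain the high Hsd3b5 and was not tested.

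Among gene lists, 14 differed in their response by camera (adjusted p = 1.45e-07 to 0.0423; with an estimated correlation the adjusted p of these lists was 0.258 to 0.469, so none was called). The median differences, LXRα minus GFP mice on the log2 scale, were 1 for macrophage markers, 1.11 for matrix markers, 1.27 for cholangiocyte markers (only 5 measured, 4 higher and 1 lower), 0.627 for lymphocyte markers, 0.796 for interferon genes, 0.504 for fatty acid oxidation, 0.474 for fatty acid synthesis, 0.421 for cell cycle and 0.237 for xenobiotic genes. They were -0.984 for acute phase genes, -0.654 for glucose metabolism, -0.514 for bile acid genes, -0.462 for clock output and -0.345 for hepatocyte markers. For macrophage markers the LXRα and GFP groups differed by a median of -1.17 under vehicle and -0.09 under T0901317. For matrix markers these medians were -0.85 and 0.18, so both list differences come mainly from the vehicle groups. Acute phase genes were led by Saa4 at -2.58 and Cxcl1 at -2.31, and interferon genes by Ifit2 at 1.82 and Gbp2 at 1.65. The 2 LXRα T0901317 arrays differed for interferon genes, with medians of 0.668 on the lower-ratio and -0.0239 on the higher-ratio array, and for lymphocyte markers, with -0.0667 and 0.661. With the β-actin covariate the interferon fall in GFP mice was at a camera adjusted p of 0.652.

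For the macrophage markers, 17 of 18 were lower in LXRα than in GFP vehicle livers. A lower share of all cells other than hepatocytes would lower endothelial markers alike. The macrophage mean lay -1.04 from the endothelial mean (permutation p = 0.00104 for the difference of means, 18 and 12 genes, which takes genes as independent). The macrophage median lay -0.965 from the endothelial one, but by single pairs of arrays this gap ran from -0.409 to -1.78. Of 15 matrix markers, 14 were lower too, with a median of -0.85. Lymphocyte markers, with 6 of 14 higher, and erythroid markers, with 3 of 5 higher, had medians of -0.08 and 0.05. A lower share of all cells other than hepatocytes is left open. Loss of 5' signal is left open as well, because the spread between arrays is wide. With each of 6 control 3'/5' ratios as a covariate the median stayed between -1.17 and -1.08. The β-actin covariate, however, moved the log2 changes of this comparison by a median of only 0.0357, and with pyruvate carboxylase, which moved them by 0.193, the list mean per array differed by -1.04 (SE 0.895), 1.16 times its SE. In GFP T0901317 arrays, with higher ratios, the median was -0.26, at -0.706 and -0.111 on single arrays. Without LXRα vehicle replicate 2 the median was -0.62, and -1.9 without replicate 1, so 1 array alone does not carry it, although its size depends on the array. Fewer or less active macrophages in these 2 livers may also explain it, which was not tested.

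The β-actin 3'/5' ratio reached 36.3 and that of dap, a bacterial control transcript, 21.8 on LXRα T0901317 replicate 2, above every vehicle array, and control ratios are not used in the comparisons. Of probe sets picked in GFP mice alone as higher after T0901317 (490), the lower-ratio LXRα array showed 0.407 of the median rise on the higher-ratio one (0.342 against 0.84), so loss of 5' signal and the agonist cannot be told apart for them. Of those picked as lower (409) it showed 0.101 (-0.133 against -1.31), as loss of 5' signal would give. Across 15838 probe sets the T0901317 effect in GFP mice correlated at r = 0.485 with the difference between the 2 LXRα T0901317 arrays and at 0.206 with the effect on the lower-ratio array (Spearman 0.315 and 0.284). Much of what falls after T0901317 in GFP mice may therefore be RNA or labelling quality. For the LXR targets loss of 5' signal and the agonist cannot be told apart either, since the ratios go with the treatment and the spread is wide. With each of the 6 control ratios as a covariate their median was between 0.443 and 1.51 in GFP mice, against 0.27 without, and between 0.777 and 1.14 in LXRα mice, against 0.70. The rise of the list mean per array was as low as 1.74 times its SE in GFP mice, with pyruvate carboxylase, and 2.18 times in LXRα mice, with dap. Their median was 0.75 on the lower-ratio and 0.665 on the higher-ratio LXRα array. A difference in handling shared by all 4 T0901317 arrays, which had the lowest 18S signal, would go with the treatment, and no fit removes it.

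Of the 35 splits of 8 arrays into 4 and 4, 1 gave as many calls as T0901317 against vehicle. It was the real split itself, with 302 calls in a 2-group fit against a highest other of 0. A share of 1 in 35 is the smallest this test can give, and every other split mixes T0901317 and vehicle arrays within an arm. The test therefore excludes neither chance nor RNA quality, which follows the same split. For LXRα against GFP all 35 of 35 gave at least its 0 calls (limma, 422 probe sets at an unadjusted p under 0.05 in the fit of 4 groups, where 1 was called), and the highest other was 302. Every split reaches a count of 0, so this test says nothing about the averaged transgene effect. The split with 302 is the T0901317 one, a structure of the samples.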

How the results depend on the processing

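The control ratios as covariates and the fit without the 3 higher-ratio arrays were chosen only after the result was seen. Counts of called probe sets are given for LXRα against GFP under vehicle (1), T0901317 in GFP mice (0), T0901317 in LXRα mice (4), LXRα against GFP under T0901317 (0), the interaction (1), and the averaged LXRα (1) and T0901317 (90) effects, all by limma; the cause of the moves was not tested. Quantile normalization gave 7 in LXRα mice (6 higher, 1 lower), 0 for the interaction (755 at an unadjusted p under 0.05 without it) and 32 for averaged T0901317 (22 higher, 10 lower). No filter on dim probe sets gave 11, 2, 14, 1, 8, 7 and 15 in the order above. The lower floor gave 0 for the interaction and 0 for averaged LXRα. Without an intensity trend there were 2 in LXRα mice and 2 for the interaction. With the replicate block there were 0 for the interaction and 17 for averaged T0901317, of which 13 were among the 90. With the compared groups alone there were 0 for LXRα under vehicle and 0 for T0901317 in LXRα mice. The β-actin covariate gave 1 for LXRα under T0901317, 2 for the interaction, 2 for averaged LXRα and 4 for averaged T0901317. With another control ratio averaged T0901317 gave 4 (Gapdh, thr) or 0 (pyruvate carboxylase, dap, phe). Without the 3 higher-ratio arrays there were 0 for LXRα under vehicle and 9 for T0901317 in LXRα mice. At an adjusted p under 0.10 there were 10 in GFP mice, 23 in LXRα mice and 738 for averaged T0901317. With each array left out in turn the ranges were 1 to 32, 0 to 43, 0 to 474, 0 to 5, 0 to 24, 0 to 31 and 0 to 1506, in the order above, the last number of each without GFP vehicle replicate 1 (32, 24, 31), LXRα T0901317 replicate 2 (43), LXRα T0901317 replicate 1 (474, 1506) and GFP T0901317 replicate 1 (5). Of 111 gene results, 0 of 2155 alternative values turned direction. This was largely fixed beforehand, because many of these genes were picked for groups that did not overlap. Several settings also leave the log2 change as it was. The numbers of lists called, 10, 4, 10, 6 and 14 for the first 5 comparisons, became 0 in each with an estimated correlation and 0 in each with fry, and 2 for T0901317 in GFP mice with the mean of a gene's probe sets. With each array left out in turn they ranged from 5 to 15, 1 to 7, 5 to 11, 3 to 7 and 10 to 13. Of 44 list results, 2 of 679 alternative values turned direction, both for LXRα against GFP under vehicle without LXRα vehicle replicate 2: fatty acid synthesis (camera adjusted p = 0.462) and acute phase genes (0.572), against 2.18e-07 and 1.16e-06 without LXRα vehicle replicate 1. The labels do not say whether replicate numbers pair the animals. Residuals of arrays with the same number correlated at -0.138 to 0.247 over 6 pairs of groups, which cannot decide it with 2 arrays per group.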

Other observations

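The list tests of the averaged comparisons and the fit without the 3 higher-ratio arrays were tests chosen only after the result was seen. In livers of LXRα vehicle mice, acute phase genes were higher in 20 of 27 members, with a median of 0.46 and with Nfkbia at 0.69, Vcam1 at -1.46, Fgg at 0.46 and Saa4 at 1.11 (camera adjusted p = 0.0214; adjusted p = 0.552 with an estimated correlation). The camera call was lost without GFP vehicle replicate 1 (0.212), without the 3 higher-ratio arrays (0.112) and after quantile normalization (0.0629), and turned direction without LXRα vehicle replicate 2 (0.572). Hepatocyte markers had a median of 0.15 (camera adjusted p = 0.0921), and Cps1, the first enzyme of the urea cycle, rose by 0.89, adjusted over the list alone (list-adjusted p = 0.0293). Lymphocyte markers, 5 of which encode antigen presentation or pan-leukocyte genes also expressed by macrophages, had a median of -0.08 with Cd74 at -1.57, H2-Aa at -2.29, H2-Ab1 at -1.70, H2-Eb1 at -1.09 and Ptprc at -1.4 (camera adjusted p = 0.0321; adjusted p = 0.523 with an estimated correlation). That call was lost without GFP vehicle replicate 1 (0.164), LXRα vehicle replicate 2 (0.217) either LXRα T0901317 array (0.06) and the 3 higher-ratio arrays (0.126). ER stress genes had a median of 0.24 with Xbp1 at 0.92 and Calr at 0.76 (camera adjusted p = 0.0921), and clock output genes one of 0.44 with Dbp at 1.52 (0.0908). Interferon genes were at -0.31 with Gbp2 at -1.29 (0.0598) and cholangiocyte markers at -0.28 with Krt18 at -1.19 (0.0598). Sterol synthesis genes were at 0.04 with Hmgcs1 at -0.78 (0.758), lipoprotein genes at 0.16 with Apom at 0.72 (0.778), glucose metabolism genes at 0.19 with G6pc at 1.02 (0.483) and erythroid markers at 0.05 with Ank1 at 0.26 (0.503).

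After T0901317 in GFP mice, whose 2 arrays had β-actin 3'/5' ratios of 7.56 and 11, clock output genes were higher in 12 of 13 members, with a median of 0.59 and with Nr1d2 at 0.84, Per2 at 1.42, Usp2 at 1.63 and Tef at 0.59 (camera adjusted p = 0.042; adjusted p = 0.896 with an estimated correlation). The call was lost without GFP vehicle replicate 1 (0.128), without GFP T0901317 replicate 2 (0.0884), with the β-actin ratio as a covariate (0.241), with the filter at the 50th percentile (0.104) and with the replicate block (0.0526). Cps1 rose by 0.99, adjusted over the list alone (list-adjusted p = 0.0159). Serum amyloid genes had differences of 3.27 for Saa2 and 2.58 for Saa1 without passing, and the acute phase list was not called (camera adjusted p = 0.191). Sterol synthesis genes had a median of 0.26 with Sqle at 0.96 and Idi1 at 0.92 (camera adjusted p = 0.191), and the list medians on the 2 arrays had opposite signs, at -0.153 and 0.817. In LXRα mice, whose arrays had ratios of 2.75 and 36.3, Krt8, a keratin, rose by 1.48 and Fbp1, a gluconeogenic enzyme, fell by 0.95 on the log2 scale, adjusted over their lists alone (list-adjusted p = 0.0452 and 0.0213). Glucose metabolism genes (camera adjusted p = 0.153), cholangiocyte markers (0.182), lymphocyte markers (0.207), interferon genes (0.218), sterol synthesis genes (0.324), lipoprotein genes (0.701), ER stress genes (0.207), clock output genes (0.89) and erythroid markers (0.0586) were not called there.

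Averaged over the transgenes, fatty acid synthesis genes were higher after T0901317 with a median of 0.49 (camera adjusted p = 0.00899), matrix markers with 0.72 (0.000644) and endothelial markers with 0.33 (0.034), each at an adjusted p of 0.771 with an estimated correlation. In GFP mice alone matrix markers had a median of -0.04 with 7 of 15 higher (camera adjusted p = 0.668), against 1.27 in LXRα mice, so their averaged rise comes from LXRα mice. The LXRα vehicle arrays were low for these markers, at a median of -0.85 against GFP vehicle livers. Under T0901317 the LXRα and GFP groups differed by a median of 0.18, so that rise comes mainly from the low LXRα vehicle values. Endothelial markers were at 0.23 (0.20) and fatty acid synthesis genes at 0.335 (0.191) in GFP mice. Pdia4 and Sdf2l1, chaperones of the endoplasmic reticulum, fell by 0.77 and 2.02 on the log2 scale, and Nr0b2 and Slco1b2 by 1.22 and 1.08, adjusted over their lists alone. Without the 3 higher-ratio arrays, the LXR targets stood at a camera adjusted p of 0.000744 in LXRα mice, and matrix markers at 9.16e-06, while with an estimated correlation both had an adjusted p of 0.493 in the fit of all arrays; the 1 T0901317 array left in that fit also had control ratios above every vehicle array.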
